A study of Homo sapiens with 9 samples.

How the data were processed

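The study measured polyadenylated RNA of sorted human umbilical artery smooth muscle cells (SMCs) by paired-end sequencing on an Illumina NovaSeq, per the labels' protocols. The 9 libraries, 3 per group, are SMCs alone, SMCs after 24 h with human mesenchymal stem cells (hMSCs) and SMCs after 24 h with hMSCs first exposed to MoS2 nanoflowers. Reads were aligned with STAR to hg38, per the submitters' processing notes. The authors deposited one table of RPKM values, with 19468 genes by gene number and symbol and one column per library, on a linear scale. The counting tool, the annotation, the lengths and the strand setting are not stated, so reads of overlapping or antisense genes cannot be told apart. The medium used during coculture is not stated either, and per the labels' protocols the hMSCs and SMCs were grown in different media.

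Whole read numbers and gene lengths were recovered from the deposited RPKM values, since each value equals reads divided by length and by the library's total. For 16351 of the 16352 genes above 0 in some library, the recovered reads were whole within 0.001 reads. The totals ranged from 34569842 to 50462898 reads, and the recovered reads add up to 99.96% of them in each library. Of the recovered lengths of expressed genes, 84.0% are multiples of 3 and 77.3% equal a coding length in GENCODE v29, and they are called coding lengths here, an inference from the values. Summed RPKM was 875386 to 883517 in SMC alone, 825801 to 849777 in the hMSC coculture and 927865 to 944216 in the MoS2-hMSC coculture. By gene number, 19421 genes matched RefSeq, which gave the coordinates on GRCh38; 864 symbols have changed since, and symbols are printed as deposited. XIST and Y-linked genes, 47 in all, were left out of every test. The 13 protein-coding genes of mitochondrial DNA and their share of expression are not analysed here.

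Genes with a mean RPKM of at least 1 over the 9 libraries were tested (11415). log2(RPKM + 1) was computed from the deposited RPKM values without further scaling and fitted with limma (lmFit, contrasts.fit, and eBayes with a variance trend), with the 3 groups in one model, no replicate block, 6 residual and 7.3 prior degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no minimum fold. Any difference among the groups was tested with the moderated F test. All libraries of one group lay on the same side of the other group for 43.8%, 50.1% and 51% of tested genes in the 3 comparisons. Chance gives this for 10% of genes with 3 against 3. It held for 3181, 4259 and 4477 of the called genes, where it largely follows from the call. A test of 3 against 3 by permutation could not go below p = 0.1 and was not used.

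For gene lists, 37 lists written from general knowledge were fixed before the data were examined, as were the design, the rule for named genes and all alternatives but those named as later; 36 have a tested member and 35 at least 2. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance or, as a mixed test, in either direction, without comparing them with other genes. Adjustment was over the 35 lists within a comparison. Camera at the preset correlation called 15, 11 and 7 lists, camera at an estimated correlation 0, 0 and 0, fry 23, 18 and 13, and fry's mixed test 33, 33 and 31. Median, mean and tests differed in sign for 8, 8 and 10 lists, 0 of which camera called. LIF, RUNX2 and VCAM1 are among the genes that stand in more than one list.

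The genes named are the 8 with the largest rise and the 8 with the largest fall in each comparison, among called genes whose libraries do not overlap and whose mean is at least 5 RPKM in the higher group, filled up by smallest p; up to 3 members with the smallest p of each list that camera called or that held at least 3 called genes; the 3 with the smallest p of the biogenesis, dynamics, contractile and antioxidant lists; and PPARGC1A, TFAM, RHOT1, GJA1, ACTA2, TAGLN, CNN1 and MYH11. Genes near 0 in one group, in the closing part, were chosen after their values were seen.

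The model was tested on simulated log2 values, drawn from a normal distribution around each gene's real mean with its fitted spread, with 67, 67 and 66 of 11415 genes changed by 1, 0.5 and 0.25 on the log2 scale. For the hMSC coculture against SMC alone it recovered 100%, 91% and 48.5% of them with 4 false calls, for the MoS2-hMSC coculture against SMC alone 100%, 92.5% and 34.8% with 11, and for the cocultures against each other 100%, 95.5% and 40.9% with 10. The TCA cycle list shifted by 0.2 was called in each comparison, and 0 of 34 other lists were. Simulated genes were drawn independently, so this cannot show how often camera at the preset correlation makes false calls among correlated genes. In the data the estimated correlation was, for example, 0.075 for complex I and 0.247 for matrix genes.

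Alternatives changed one choice at a time: pseudocounts of 0.1 and 0.01, no filter, a mean RPKM of at least 5, rescaling to a common sum, median-ratio scaling, quantile normalization, no variance trend, robust eBayes, library weights, only the 2 groups compared, the replicate number as a block, a minimum log2 difference of 1, and each library left out in turn. Chosen after seeing the data were voom on the recovered reads and removal of each library's trend on coding length, a loess of its log2 deviation from the gene mean. Random lists matched on coding length and mean expression, also chosen after seeing the data, were drawn 10000 times from the 100 nearest genes of each member. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.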

Results

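Gene expression was measured by paired-end sequencing of polyadenylated RNA from human umbilical artery smooth muscle cells (SMCs), the contractile cells of the artery wall. The 9 libraries form 3 groups of 3: sorted SMCs kept alone, SMCs sorted after 24 h with human mesenchymal stem cells (hMSCs), and SMCs sorted after 24 h with hMSCs first exposed to molybdenum disulfide (MoS2) nanoflowers. These last 2 groups are called the hMSC coculture and the MoS2-hMSC coculture. The series concerns a nanomaterial that induces mitochondrial biogenesis and the passage of mitochondria from one cell to another. Expression is given in RPKM, reads per kilobase of coding length scaled to each library's read total. The read totals behind these values were 50462898, 47999809 and 40887401 in SMC alone, 34569842, 35230798 and 38972740 in the hMSC coculture, and 39810986, 39350553 and 38331817 in the MoS2-hMSC coculture. Errors of means are SDs over n = 3 libraries, and errors of log2 differences are standard errors from limma. The labels call the SMC-alone libraries biological replicates and the coculture libraries replicates. The p-values weigh differences between groups against the spread of these libraries within groups. The sample titles name no donor or culture day, so how far the p-values hold for other donors is not known.

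The 3 groups differed in a large share of their expressed genes, mostly by small amounts. Of 11415 genes tested, 6287 (55.1%) differed among the groups by limma's moderated F test. The first principal component, with 40.5% of the variance, set SMC alone (-15.8 to -12.2), the hMSC coculture (-0.74 to 3.21) and the MoS2-hMSC coculture (12.9 to 13.8) apart. The second, with 32.3%, separated the hMSC coculture from the other groups. The hMSC coculture had 1476 genes higher and 1814 lower than SMC alone, the MoS2-hMSC coculture 2119 higher and 2280 lower than SMC alone, and the MoS2-hMSC coculture 2178 higher and 2495 lower than the hMSC coculture. These balances depend on scaling: with libraries rescaled to the same sum the counts were 2858 and 1144, 1236 and 3746, and 1059 and 5719. The median absolute log2 difference of these genes was 0.26, 0.27 and 0.28 in the 3 comparisons. Differences of at least 1 on the log2 scale were found for 31 higher and 40 lower genes, 32 higher and 37 lower genes, and 4 higher and 2 lower genes, in the same order. The calls also depend on coding length. Of the 3290, 4399 and 4673 genes called, 2420, 3116 and 2146 were also called with each library's trend on coding length removed.

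The first comparison sets SMCs sorted after 24 h beside untreated hMSCs against SMC alone. No library of hMSCs alone is used here. For genes higher in either coculture, RNA from hMSCs in the sorted fraction cannot be told from a rise in SMCs. By camera at its preset correlation, matrix, cell cycle and immediate early genes were higher, and genes of lysosomes, mitophagy, oxidant defence, and p53 and senescence were lower. With an estimated correlation, 0 lists were called. ELN, which encodes elastin, rose from 0.231 ± 0.0819 RPKM to 21.8 ± 2.31 RPKM (log2 difference 4.21 ± 0.09, adjusted p = 3.17e-12). MFAP5, a protein of elastic microfibrils, rose from 0.693 ± 0.498 to 22.05 ± 1.32 RPKM (log2 difference 3.80 ± 0.15, adjusted p = 2.2e-09). NPPB, which encodes the natriuretic peptide BNP, fell from 43.2 ± 4.0 to 4.37 ± 0.426 RPKM (log2 difference -3.04 ± 0.08, adjusted p = 3.57e-11). By RefSeq on GRCh38, ELN (gene 2006) lies on chromosome 7 from 74028173 to 74069907, MFAP5 (gene 8076) on chromosome 12 from 8645943 to 8662826, and NPPB (gene 4879) on chromosome 1 from 11857464 to 11858945.

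The other genes with the largest rises were ISLR, from 0.696 ± 0.33 to 11.5 ± 0.65 RPKM, the keratin KRT7, from 1.27 ± 0.362 to 9.83 ± 0.277 RPKM, the collagen-binding integrin subunit ITGA11, from 1.13 ± 0.0779 to 7.23 ± 0.854 RPKM, ITGBL1, CRIP1 and the immediate early gene FOSB. The other genes with the largest falls were the acute phase genes SAA1, from 100.9 ± 6.44 to 16.9 ± 3.09 RPKM, and SAA2, the protease inhibitors SERPINB2, from 265.2 ± 29.6 to 52.3 ± 1.31 RPKM, SLPI and PI3, and TINAGL1 and CPA4. SAA1 and SAA2 are near-identical copies, so the split of reads between them is uncertain.

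Of the 24 extracellular matrix genes tested, 19 rose and 2 fell, the same counts adjusted over the list alone, with a median log2 difference of 0.22 (camera adjusted p = 9.61e-10, and adjusted p = 0.112 with an estimated correlation). BGN, which encodes the proteoglycan biglycan, rose from 18.5 ± 1.26 to 48.8 ± 3.89 RPKM, while LOX, the enzyme that crosslinks collagen and elastin, fell from 348.4 ± 28.6 to 202.3 ± 10.3 RPKM. Of 16 targets of TGF-beta and YAP, which control growth and matrix production, 10 rose and 1, ANKRD1, fell (median 0.19; 10 and 1 adjusted over the list alone, camera adjusted p = 1.35e-04, and adjusted p = 0.112 with an estimated correlation). Among 15 matrix proteases and their inhibitors, 3 rose and 8 fell (3 and 9 adjusted over the list alone; median -0.12, camera adjusted p = 0.0115, and adjusted p = 0.112 with an estimated correlation). The 3 members with the smallest p were TIMP3, an inhibitor, which fell from 742.3 ± 128 to 245.8 ± 27.8 RPKM, the plasminogen activator PLAT, which fell from 1421 ± 123 to 643.3 ± 33.3 RPKM, and the collagenase MMP1, which fell from 6.50 ± 0.59 to 2.72 ± 0.276 RPKM. The call of this list ended without hMSC coculture replicate 2 (adjusted p = 0.0542), with a mean RPKM of at least 5 (0.0615) and after quantile normalization (0.25), and its lowest adjusted p over the alternatives was 0.00425.

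Of 31 cell cycle genes, 18 rose and 0 fell, or 23 and 0 adjusted over the list alone (median 0.19, camera adjusted p = 1.2e-08, and adjusted p = 0.112 with an estimated correlation). The replication helicase subunits MCM7, MCM2 and MCM5 rose by 0.32 ± 0.04, 0.31 ± 0.05 and 0.27 ± 0.04 on the log2 scale. Of 17 p53 and senescence genes, 1 rose and 8 fell, the same counts adjusted over the list alone (median -0.25, camera adjusted p = 0.00287, and adjusted p = 0.0871 with an estimated correlation). They include the inhibitors CDKN2A, which fell from 173.7 ± 11.2 to 78.9 ± 4.22 RPKM, and CDKN1A, which fell from 186.6 ± 2.84 to 148.7 ± 4.48 RPKM. Of 10 replication-dependent histone genes, 1 rose and 7 fell, 8 adjusted over the list alone (median -0.65, camera adjusted p = 3.46e-04, and adjusted p = 0.0645 with an estimated correlation). HIST1H2AC fell from 32.9 ± 2.77 to 13.1 ± 0.305 RPKM, with the reserve that reads of these near-identical genes are hard to assign.

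Immediate early genes, which answer growth signals and also cell dissociation, rose in 14 of 22 cases and fell in 1 (15 and 1 adjusted over the list alone; median 0.47, camera adjusted p = 3.51e-07, and adjusted p = 0.0645 with an estimated correlation). FOS rose from 22.0 ± 3.14 to 65.4 ± 19.6 RPKM and ATF3 from 10.8 ± 1.34 to 23.7 ± 0.354 RPKM. The 28 tested genes of inflammatory cytokines and NF-kB signalling split, with 9 higher and 10 lower (12 and 10 adjusted over the list alone), a median of 0.06, a mean of -0.23 and no call by camera (adjusted p = 0.611). Fry called the list lower (adjusted p = 0.00265). The chemokines CCL20 and CCL2 fell by 1.76 ± 0.08 and 1.60 ± 0.09 on the log2 scale and the cytokine IL1B fell by 1.31 ± 0.06, from 336.1 ± 2.99 to 135.1 ± 13.7 RPKM.

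Genes of mitochondrial clearance, lysosomes and oxidant defence were lower in the hMSC coculture. Of 15 mitophagy genes 9 fell and 0 rose, 10 and 0 adjusted over the list alone (median -0.22, camera adjusted p = 9.89e-05, and adjusted p = 0.0645 with an estimated correlation). PINK1, the kinase that marks damaged mitochondria, fell from 50.9 ± 2.25 to 36.9 ± 1.23 RPKM, and the autophagy receptor SQSTM1 from 378.5 ± 33.9 to 242.4 ± 6.43 RPKM. Of 21 lysosomal genes 13 fell and 0 rose, 15 and 0 adjusted over the list alone (median -0.17, camera adjusted p = 6.74e-06, and adjusted p = 0.06 with an estimated correlation), among them the cathepsins CTSB, CTSD and CTSZ. Of 22 NRF2 and antioxidant genes 14 fell and 2 rose, 16 and 3 adjusted over the list alone (median -0.20, camera adjusted p = 1.49e-05, and adjusted p = 0.167 with an estimated correlation). SOD2, the superoxide dismutase of mitochondria, fell from 257.8 ± 10.3 to 143.4 ± 5.26 RPKM and TXNRD1 from 330.1 ± 1.07 to 215.2 ± 6.45 RPKM.

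Nuclear genes of the respiratory chain were slightly lower in the hMSC coculture than in SMC alone. In complex I, 14 of 37 fell and 0 rose (17 and 0 adjusted over the list alone; median -0.11), in complexes II to IV 14 of 25 fell and 0 rose (14 and 0; median -0.15), in ATP synthase 11 of 18 fell and 1 rose (12 and 1; median -0.17), and in the mitochondrial ribosome 12 of 49 fell and 0 rose (12 and 0; median -0.08). The camera adjusted p-values were 3.46e-04, 2.53e-06, 3.46e-04 and 0.00198, and the adjusted p-values with an estimated correlation were 0.167, 0.181, 0.199 and 0.41. Most of these genes are short, and log2 differences rose with coding length across all genes in this comparison (Spearman's rho 0.34 across 11415 genes, which are not independent replicates). With each library's trend on coding length removed, complexes II to IV passed (camera adjusted p = 0.0201, the highest over the alternatives, with a lowest of 1.14e-07), and complex I, ATP synthase and the mitochondrial ribosome did not (adjusted p = 0.411, 0.252 and 0.62). Those 3 lists also did not pass after quantile normalization (adjusted p = 0.059, 0.0728 and 0.139), and their lowest adjusted p-values over the alternatives were 5.28e-05, 8.81e-05 and 1.4e-04. The medians of all 4 lists lay within the central 95% of random lists matched on coding length and mean expression, at percentiles 36.7 for complex I, 16.32 for complexes II to IV, 12.54 for ATP synthase and 51.35 for the mitochondrial ribosome.

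Regulators of mitochondrial biogenesis and genes of mitochondrial dynamics and transport were not called by camera in any of the 3 comparisons. Fry, which does not compare a list with other genes, called the biogenesis regulators higher in the hMSC coculture than in SMC alone (adjusted p = 0.0137). Its mixed test called both lists in each comparison (adjusted p of at most 8.13e-04). After the hMSC coculture 5 of 21 biogenesis regulators rose and 1 fell (median 0.05, camera adjusted p = 0.289), and 2 of 22 dynamics and transport genes rose and 2 fell (median -0.004, camera adjusted p = 0.987). TFAM, which packages and transcribes mitochondrial DNA, averaged 51.4 ± 4.29 RPKM in SMC alone and 57.4 ± 2.25 RPKM in the hMSC coculture (log2 difference 0.16 ± 0.06, adjusted p = 0.0451), a call that was lost under 12 of 23 alternatives (adjusted p from 0.00396 to 0.177). GJA1, the gap junction protein connexin 43, fell from 296.7 ± 3.59 to 222.4 ± 6.29 RPKM (adjusted p = 1.54e-06), and RHOT1, which links mitochondria to their motors, averaged 15.8 ± 0.914 and 16.0 ± 1.56 RPKM (adjusted p = 0.92). Contractile genes of SMCs split, with 5 of 15 higher and 5 lower (median -0.07, camera adjusted p = 0.909): ACTA2, smooth muscle actin, rose from 147.1 ± 6.65 to 190.1 ± 7.49 RPKM and TAGLN fell from 1871 ± 127 to 1570 ± 42.3 RPKM. CNN1 was lower (log2 difference -0.289, adjusted p = 0.0318), a call lost under 9 of 23 alternatives. PPARGC1A and MYH11 had a mean below 1 RPKM and were not tested. The number of higher genes in this comparison, 1476, was 906 without SMC-alone replicate 3 and 955 without hMSC coculture replicate 3.

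**Figure D1:**
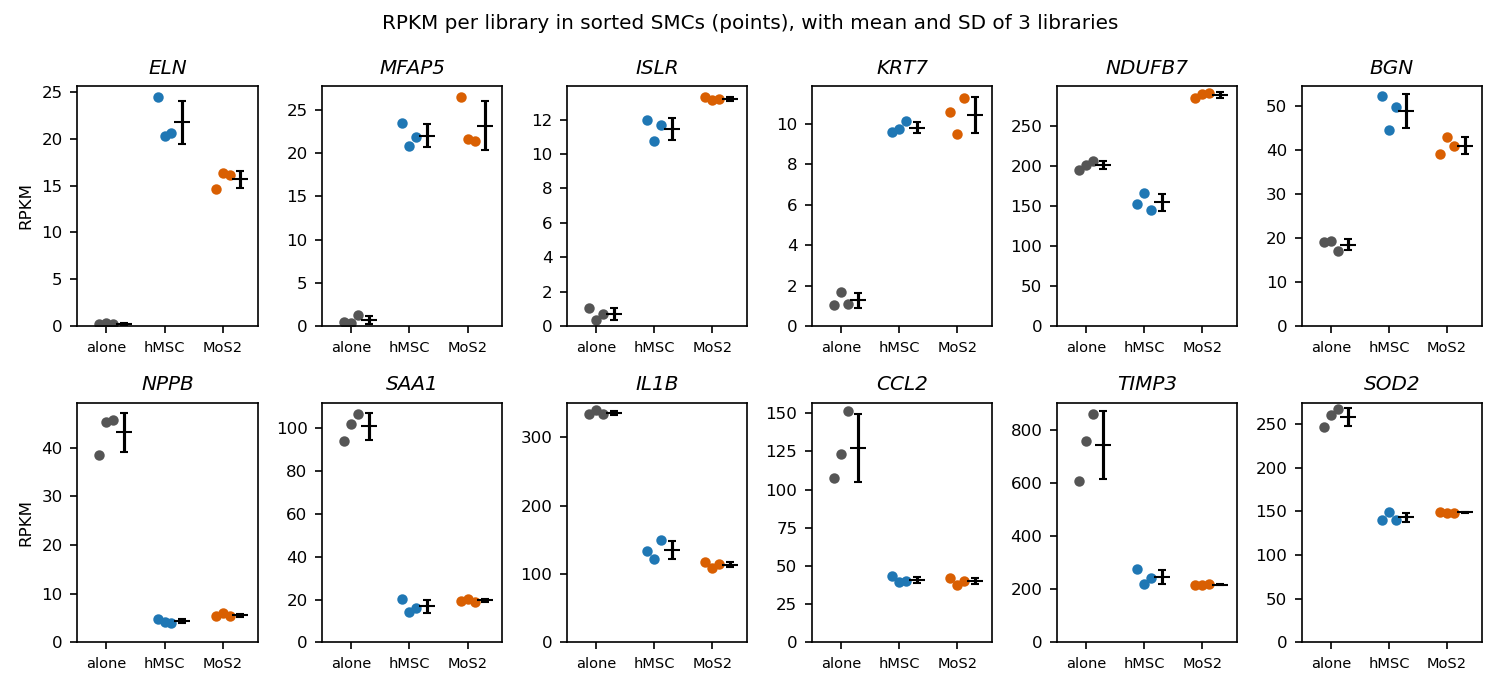
RPKM of 12 genes in each of the 9 libraries (points), with the mean and SD of each group beside them; on the x axis, alone is SMC alone, hMSC the hMSC coculture and MoS2 the MoS2-hMSC coculture. The 3 libraries of SMC alone lie apart from both cocultures for ELN, MFAP5, NPPB and IL1B, and NDUFB7 differs between the cocultures, with means of 154.4 and 288.6 RPKM.

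The second comparison sets SMCs sorted after 24 h beside the nanoflower-treated hMSCs against SMC alone. Genes of the respiratory chain and of the mitochondrial ribosome were higher here by camera at its preset correlation, and again 0 lists were called with an estimated correlation. Their slightly lower medians after the hMSC coculture lay within random lists matched on coding length and mean expression. Log2 differences rose with coding length in that comparison and fell with it in this one (Spearman's rho 0.34 and -0.36). ELN rose to 15.7 ± 0.905 RPKM (log2 difference 3.76 ± 0.09, adjusted p = 1.39e-11) and MFAP5 to 23.2 ± 2.84 RPKM (3.87 ± 0.15, adjusted p = 2.06e-09). NPPB fell to 5.55 ± 0.358 RPKM (-2.75 ± 0.08, adjusted p = 1.98e-10). The complex I subunit NDUFB7 (gene 4713, chromosome 19 from 14566078 to 14572066) rose from 200.8 ± 5.41 to 288.6 ± 3.54 RPKM (log2 difference 0.52 ± 0.05, adjusted p = 3.16e-06).

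Of the nuclear respiratory genes, 29 of 37 rose in complex I (30 adjusted over the list alone; median 0.23), 17 of 25 in complexes II to IV (19; median 0.21) and 13 of 18 in ATP synthase (13; median 0.20), and 37 of 49 mitochondrial ribosome genes rose (38; median 0.23), with 0 lower in each list. The camera adjusted p-values were 1.99e-10, 2.29e-09, 1.18e-07 and 1.41e-12, and the adjusted p-values with an estimated correlation 0.109, 0.141, 0.141 and 0.141. COX7B, a subunit of cytochrome c oxidase, rose from 174.1 ± 3.51 to 277.7 ± 18.7 RPKM. CYC1, cytochrome c1, rose from 197.3 ± 6.89 to 264.4 ± 5.17 RPKM and the mitochondrial ribosome protein MRPL24 from 105.8 ± 5.2 to 145.9 ± 2.35 RPKM. Other members with the smallest p were NDUFS5, UQCRB, USMG5, ATP5E, MRPS34 and MRPL51. Log2 differences fell with coding length in this comparison (Spearman's rho -0.36 across genes). With each library's trend on length removed, all 4 lists still passed, with lower medians of 0.10, 0.08, 0.08 and 0.14 and 15, 11, 9 and 27 members higher (camera adjusted p = 1.77e-04, 0.00263, 0.00377 and 3.34e-07). These were the highest values over each list's alternatives, and the lowest were 1.13e-12, 6.49e-11, 2.61e-09 and 1.1e-15. Against random lists matched on length and mean expression, complex I (percentile 99.34) and the mitochondrial ribosome (99.99) lay above the central 95%. Complexes II to IV (91.24, random lists 0.053 to 0.251) and ATP synthase (85.02, random lists 0.036 to 0.256) lay within it.

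Of 21 biogenesis regulators 5 rose and 1 fell (median 0.02, camera adjusted p = 0.578). TFAM rose to 63.0 ± 0.977 RPKM (log2 difference 0.29 ± 0.06, adjusted p = 0.00113) and TEFM, a factor of mitochondrial transcription elongation, rose from 14.2 ± 1.32 to 18.7 ± 0.301 RPKM (adjusted p = 0.00216). Of 22 dynamics and transport genes 4 rose and 6 fell (median 0.01, camera adjusted p = 0.997). FIS1, a receptor in mitochondrial fission, rose from 280.2 ± 8.09 to 362.2 ± 13.1 RPKM, GJA1 fell to 226.7 ± 2.48 RPKM (adjusted p = 2.47e-06), and RHOT1 averaged 17.6 ± 1.37 RPKM (adjusted p = 0.168).

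The integrated stress response, which raises amino acid synthesis through the transcription factor ATF4, was higher. Of 20 genes 12 rose and 2 fell, 12 and 3 adjusted over the list alone (median 0.20, camera adjusted p = 0.017, and adjusted p = 0.278 with an estimated correlation). ATF4 itself rose from 309.6 ± 3.39 to 423.0 ± 5.2 RPKM and SHMT2, a mitochondrial enzyme of serine use, from 148.0 ± 2.23 to 180.0 ± 3.9 RPKM. Immediate early genes rose in 12 of 22 cases and fell in 2, the same counts adjusted over the list alone (median 0.29, camera adjusted p = 4.68e-04, and adjusted p = 0.141 with an estimated correlation), with ATF3 at 32.6 ± 3.5 RPKM. Of 31 cell cycle genes 17 rose and 0 fell, 17 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 6.26e-06, and adjusted p = 0.22 with an estimated correlation). CDC20, which drives exit from mitosis, rose from 182.9 ± 4.14 to 248.3 ± 5.76 RPKM.

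Lysosomal genes were lower, with 13 of 21 down and 0 up, also adjusted over the list alone (median -0.16, camera adjusted p = 3.9e-04, and adjusted p = 0.109 with an estimated correlation). Of 15 matrix proteases and inhibitors 8 fell and 0 rose, 9 and 0 adjusted over the list alone (median -0.15, camera adjusted p = 0.00683, and adjusted p = 0.141 with an estimated correlation). TIMP3 fell to 216.7 ± 2.13 RPKM and PLAT to 715.5 ± 20.6 RPKM. Of 10 replication-dependent histone genes 7 fell and 1 rose, also adjusted over the list alone (median -0.52, camera adjusted p = 0.0115, and adjusted p = 0.141 with an estimated correlation), with HIST1H2AC at 15.5 ± 0.614 RPKM. The histone call was lost with no filter (adjusted p = 0.177), with a mean RPKM of at least 5 (0.212), with libraries rescaled to the same sum (0.073) and with voom (0.0822), and its lowest adjusted p over the alternatives was 6.98e-04. Of the 3 tested endothelial markers, TEK, EGFL7 and KDR, all 3 fell (median -0.42, camera adjusted p = 0.0248, and adjusted p = 0.141 with an estimated correlation). In the hMSC coculture TEK and EGFL7 were lower (median -0.39, camera adjusted p = 0.0138, and adjusted p = 0.112 with an estimated correlation). These marker calls were lost with no filter (adjusted p = 0.4 and 0.263), with lowest values over the alternatives of 0.0199 and 0.0056, and the first also with libraries rescaled to the same sum (0.0703).

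Camera did not call the groups that follow, while fry called antioxidant genes (adjusted p = 0.00323) and inflammatory genes (adjusted p = 0.0035) lower. Matrix genes had 5 of 24 higher and 10 lower, with a median of -0.06, a mean of 0.13 and a camera adjusted p of 0.58 (0.00411 to 0.69 over the alternatives). Quantile normalization called this list lower (adjusted p = 0.00411), and removal of the trend on length called it higher (adjusted p = 0.00586). Inflammatory genes had 13 of 28 higher and 11 lower (median 0.01, mean -0.20, camera adjusted p = 0.774): IL1B fell to 113.9 ± 4.05 RPKM and CCL2 to 40.1 ± 2.17 RPKM. Among 22 antioxidant genes 3 rose and 9 fell (median -0.08, camera adjusted p = 0.249). Removal of the trend on length (adjusted p = 0.0163) and quantile normalization (0.0138, the lowest over the alternatives, with a highest of 0.346) called this list lower, with its median below matched random lists (percentile 0.3). SOD2 was down to 148.9 ± 0.736 RPKM and AKR1C1 up from 32.2 ± 4.4 to 63.7 ± 2.32 RPKM. AKR1C1 and AKR1C2, which rose from 2.10 ± 0.182 to 11.6 ± 1.41 RPKM, are close paralogs, so the split of their reads is uncertain. Contractile genes had 3 of 15 higher and 4 lower (median 0.02, camera adjusted p = 0.774), with ACTA2 up to 179.3 ± 2.79 RPKM and CNN1 not called (log2 difference 0.019, adjusted p = 0.89). HAS1, a hyaluronan synthase, rose from 12.4 ± 1.36 to 44.0 ± 0.893 RPKM.

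The direct comparison of the cocultures sets treated against untreated hMSCs as partners. Nuclear genes for respiration and mitochondrial translation were higher in SMCs after the MoS2-hMSC coculture, and matrix genes and targets of TGF-beta and YAP were lower, by camera at its preset correlation. With an estimated correlation 0 lists were called, and the matrix call was lost with the trend on coding length removed (adjusted p = 0.156, the highest over the alternatives, with a lowest of 2.08e-15). NDUFB7 rose from 154.4 ± 10.9 to 288.6 ± 3.54 RPKM (log2 difference 0.90 ± 0.05, adjusted p = 6.44e-08). COX7B rose from 151.3 ± 7.52 to 277.7 ± 18.7 RPKM (0.87 ± 0.05, adjusted p = 1.11e-07) and MRPL32 from 105.7 ± 8.73 to 172.0 ± 2.22 RPKM (0.70 ± 0.05, adjusted p = 5.93e-07). TIMM8B, which helps import proteins into mitochondria (gene 26521, chromosome 11 from 112084800 to 112086756), rose from 164.8 ± 3.04 to 345.0 ± 20.3 RPKM (log2 difference 1.06 ± 0.06, adjusted p = 1.03e-07).

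In complex I 30 of 37 genes were higher and 0 lower (33 and 0 adjusted over the list alone; median 0.33), in complexes II to IV 22 of 25 and 0 (22 and 0; median 0.36), in ATP synthase 14 of 18 and 0 (15 and 0; median 0.28), and in the mitochondrial ribosome 40 of 49 and 0 (40 and 0; median 0.32). The camera adjusted p-values were 4.64e-15, 4.64e-15, 5.84e-11 and 8.27e-17, and the adjusted p-values with an estimated correlation 0.0905, 0.107, 0.107 and 0.107. Across genes the log2 difference fell with coding length more steeply here than in the other comparisons (Spearman's rho -0.61): its median was 0.23 in the shortest decile of genes, with 635 higher and 31 lower, and -0.27 in the longest decile, with 3 higher and 813 lower. With each library's trend on length removed, the 4 lists had 19, 14, 9 and 30 members higher and 0, 3, 1 and 1 lower, medians of 0.15, 0.18, 0.11 and 0.18, and camera adjusted p-values of 1.36e-05, 1.49e-06, 5.61e-04 and 4.83e-09, each the highest over that list's alternatives. The lowest were 1.8e-18, 1.13e-17, 2.75e-13 and 3.24e-21. Against matched random lists, complex I (percentile 99.52) and the mitochondrial ribosome (100) lay above the central 95%, and complexes II to IV (96.56) and ATP synthase (70.9) lay within it.

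**Figure D2:**
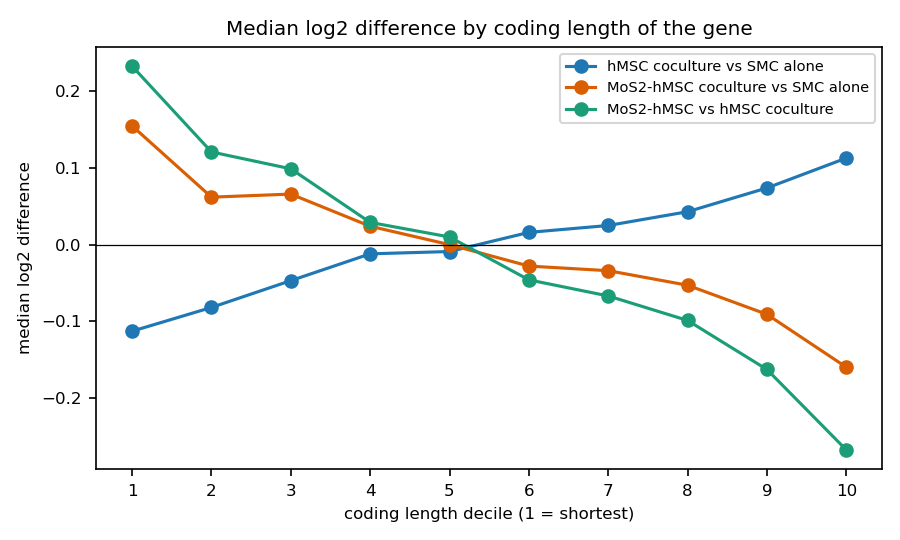
Median log2 difference (y axis) of the tested genes in each decile of coding length (x axis, shortest first), with a line for each of the 3 comparisons. The line of the direct comparison of the cocultures runs from 0.23 to -0.27, and that of the hMSC coculture against SMC alone runs the other way, from -0.11 to 0.11.

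Matrix genes were lower after the MoS2-hMSC coculture in 21 of 24 cases and higher in 1, also adjusted over the list alone (median -0.30, camera adjusted p = 4.94e-10, and adjusted p = 0.217 with an estimated correlation). FBN1, fibrillin, fell from 239.3 ± 10.8 to 181.4 ± 3.47 RPKM and COL4A1, a basement membrane collagen, from 545.9 ± 7.22 to 433.5 ± 6.8 RPKM. With the trend on length removed 7 were lower and 1 higher (median -0.06), with FBN1 at -0.02 (adjusted p = 0.75) and COL4A1 at -0.06 (adjusted p = 0.15). Yet the median of the list lay below random lists matched on length and mean expression (-0.186 to -0.063, percentile 0), so the 2 treatments of length gave different answers. The random lists had a median of -0.117, against -0.268 for the longest decile of tested genes. How close in length the genes drawn for the longest members came was not checked. The percentile therefore cannot show a fall beyond that of length. Of 16 targets of TGF-beta and YAP 11 fell and 0 rose, also adjusted over the list alone (median -0.18, camera adjusted p = 0.00242, and adjusted p = 0.281 with an estimated correlation). LTBP2, which binds latent TGF-beta complexes to the matrix, fell from 37.7 ± 2.45 to 30.5 ± 0.44 RPKM, with a log2 difference of -0.005 once the trend on length was removed (adjusted p = 0.955). With that trend removed 7 of these targets were lower and 0 higher (median -0.10, camera adjusted p = 0.016, the highest over the alternatives, with a lowest of 6.92e-05). Without that removal, the median of -0.18 lay below matched random lists (-0.118 to 0.074, percentile 0.02).

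Of 22 antioxidant genes 9 were higher and 1 lower, 9 and 3 adjusted over the list alone (median 0.10, camera adjusted p = 0.0215, and adjusted p = 0.575 with an estimated correlation). Thioredoxin, TXN, rose from 934.1 ± 59.4 to 1461 ± 96.1 RPKM and the quinone reductase NQO1 from 252.0 ± 7.12 to 313.5 ± 5.7 RPKM. This call was lost with the trend on length removed (adjusted p = 0.284), after quantile normalization (0.661), with a mean RPKM of at least 5 (0.0554) and with libraries rescaled to the same sum (0.31), where the median turned to -0.06. The lowest adjusted p over the alternatives was 0.00631, and the median lay within matched random lists (percentile 71.23). Of 21 biogenesis regulators 5 rose and 5 fell (median -0.003, camera adjusted p = 0.995). TEFM was higher by 0.56 ± 0.08 on the log2 scale (adjusted p = 1.18e-04), PPRC1 lower by a log2 difference of -0.40 ± 0.06 (adjusted p = 9.19e-05; -0.13 and adjusted p = 0.0716 with the trend on length removed) and TFAM at 0.13 ± 0.06 (adjusted p = 0.0704). Among 22 dynamics and transport genes 3 rose and 5 fell (median -0.004, camera adjusted p = 0.995). FIS1 was higher by 0.78 ± 0.04 (adjusted p = 9.76e-08), and GJA1 and RHOT1 at 0.03 ± 0.03 and 0.13 ± 0.08 (adjusted p = 0.534 and 0.202).

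Contractile genes split, with 4 of 15 higher and 4 lower (median -0.05, mean 0.03, camera adjusted p = 0.946). TAGLN was higher by 0.32 ± 0.04 (adjusted p = 1.06e-04), but -0.008 after quantile normalization, and ACTA2 differed by -0.08 ± 0.04 (adjusted p = 0.131). CNN1 was higher (log2 difference 0.307, adjusted p = 0.0172), a call lost under 4 of 23 alternatives. The cell cycle inhibitor CDKN2A rose from 78.9 ± 4.22 to 121.1 ± 3.49 RPKM, and the chemokine CXCL8 from 1884 ± 227 to 2969 ± 76.4 RPKM (adjusted p = 1.56e-05). The other genes with the largest rises were TRAPPC6A, TMSB15A, the ribosomal protein genes RPS29 and RPS27, DPM3, PFDN4 and MRPL54, all with a coding length of 522 bases or less. The genes with the largest falls were RBP5, from 9.45 ± 1.92 to 3.98 ± 1.35 RPKM, LENG8, LY6G5B, KMT2D, GNB3, NPIPB3, DST and NKTR. With the trend on length removed DST went from -0.66 to -0.09 (adjusted p = 0.179) and KMT2D from -0.71 to -0.19 (adjusted p = 0.0517), and neither was called. RPS27, RPS29 and NPIPB3 have near-identical copies, so their reads are uncertain.

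**Figure D3:**
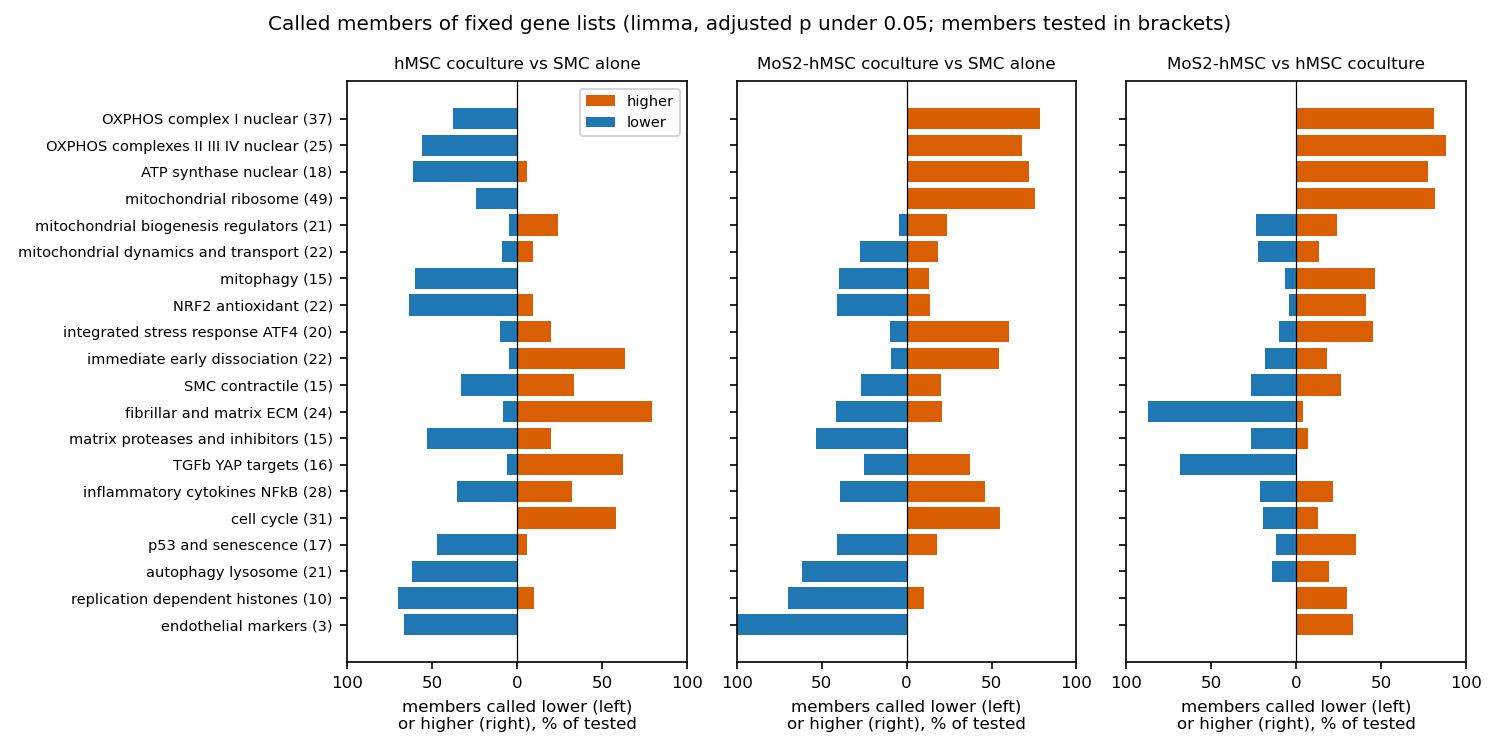
Percent of the tested members of each fixed gene list (y axis, number tested in brackets) that were called higher (orange, right) or lower (blue, left) in the 3 comparisons. Respiratory chain lists extend right in the comparisons of the MoS2-hMSC coculture (30 of 37 complex I genes against the hMSC coculture) and 19 of 24 matrix genes were higher in the hMSC coculture than in SMC alone, 5 higher and 10 lower in the MoS2-hMSC coculture than in SMC alone, and 21 lower in the direct comparison.

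The cocultures shared part of their differences from SMC alone. They had 513 genes higher and 810 lower in common, where independent lists of these sizes would share 274 and 362. Simulated unchanged groups, with all 9 libraries drawn anew and the controls shared by both comparisons, gave 0.01 in each direction. Unchanged groups give almost no calls, so the 0.01 cannot show how much of the overlap comes from shared controls. The log2 differences correlated across genes with r = 0.56 (0.501 for simulated unchanged groups), had a covariance of 0.0353 (0.00347 simulated) and had the same sign in 58.9% of genes (66.7% simulated). Correlation and covariance thus lay above the simulated values, and the share of equal signs lay below. The 3 control libraries are too few to give each comparison controls of its own, so part of the excess in shared calls may come from the shared controls. Opposite calls were made for 80 genes higher in the hMSC coculture and lower in the MoS2-hMSC coculture and 388 genes lower in the first and higher in the second. Independent lists would give 295 and 337. The median coding length of these 80 and 388 genes was 5220 and 541.5 bases, against 1412 for all tested genes.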

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

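The tests of gene length, of RNA from hMSCs and of the histone genes in this part were chosen after the results were seen, while the fit without MoS2-hMSC coculture replicate 3 and the splits of the libraries were set before. The difference between the cocultures was itself tested by limma and camera, and 7 lists passed at the preset correlation and 0 with an estimated correlation (adjusted p from 0.0905 to 0.575 for these 7). Their median log2 differences were 0.333 for complex I, 0.356 for complexes II to IV, 0.28 for ATP synthase, 0.321 for the mitochondrial ribosome, 0.098 for antioxidant genes, -0.301 for matrix genes and -0.184 for targets of TGF-beta and YAP. Against SMC alone, 80 genes were higher after the hMSC coculture and lower after the MoS2-hMSC coculture, and 388 the other way. With each library's trend on coding length removed, these counts were 26 and 164.

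Of the 129 nuclear genes of the respiratory chain, ATP synthase and mitochondrial ribosome, 106 were higher and 0 lower after the MoS2-hMSC coculture than after the hMSC coculture, while log2 differences fell with coding length across genes (rho -0.609). Random lists matched on length and mean expression were tried first on the 4 lists together (median 0.321, random lists 0.125 to 0.236). They were then tried on 2 joined pairs, chosen once each list's percentile was known and not reported here. The form kept was each list alone. Complex I lay at percentile 99.52 (median 0.333, central 95% of random lists 0.103 to 0.295) and the mitochondrial ribosome at percentile 100 (0.321, 0.089 to 0.232). This argues against coding length as their whole cause, though random medians of 0.192 and 0.146 show that it may account for part. Lists were not matched on the length of whole transcripts, so a trend on that length was not tested. Random members were drawn independently, so these ranges leave out correlation within a list. Camera at an estimated correlation called neither list (adjusted p = 0.0905 and 0.107). Complexes II to IV lay at percentile 96.56 (0.356, 0.106 to 0.367) and ATP synthase at percentile 70.9 (0.28, 0.098 to 0.401), within the random lists. Both were still called with the trend on length removed (camera adjusted p = 1.49e-06 and 5.61e-04), so length and another origin cannot be told apart for them. Without MoS2-hMSC coculture replicate 3, the library with the fewest genes above 0 (13909, against 14623 to 14908 in the others), 103 were higher, which argues against that library as the cause, and a response of SMCs to the treated hMSCs stays open, as do RNA quality and library preparation, for which no values per library are used here.

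Among genes picked after their values were seen, 10 averaged under 1 RPKM in SMC alone and at least 2 RPKM in both cocultures: MFAP5, ELN, ISLR, FNDC1, MT1M, DNER, IL1RL1, PRRX1, PRRX2 and COMP. RNA from hMSCs in the sorted fraction is a candidate explanation, although the protocol sorts the SMCs. Of 20 tested hMSC markers 7 were higher and 6 lower after the hMSC coculture (median 0.041, camera adjusted p = 0.714), while fry called the list higher (adjusted p = 0.003). Of the 7 fixed markers under 1 RPKM in SMC alone, the 2 that passed the filter, COMP and PRRX1, rose, which decides nothing because a gene so low in SMC alone passes the filter by being higher in the cocultures, and the other 5 went from 0 to 0.13 and 0.06 RPKM (DLX5), 0.23 to 0.31 and 0.18 (LRRC15), 0.58 to 0.78 and 1.07 (NGFR), 0.43 to 0.79 and 0.84 (PODXL) and 0.1 to 0.02 and 0.17 (SFRP4). RNA from hMSCs and induction in SMCs cannot be told apart for these genes, since no library of hMSCs alone is used here. The same holds for genes above that cut that rose, such as KRT7, ITGA11 and BGN.

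Replication-dependent histone genes were lower after both cocultures, with medians of -0.645 and -0.517 and 7 of 10 genes lower in each, but the list was not called with an estimated correlation (adjusted p = 0.0645 and 0.141), and the MoS2-hMSC call was also lost under 4 alternatives (adjusted p = 0.073 to 0.212, with a lowest of 6.98e-04 over all). Coding length is an unlikely cause, since both lay under the central 95% of random lists matched on coding length and expression, whose lowest values were -0.288 and -0.258. Fewer cells in S phase could lower cell cycle genes as well, but their medians were 0.186 and 0.167. By limma 18 and 17 of 31 genes were higher and 0 lower, with no call of the list by camera with an estimated correlation (adjusted p = 0.112 and 0.22). The list also holds genes of mitosis, such as CDC20, so its median cannot exclude fewer cells in S phase. Histone transcripts mostly lack a poly(A) tail, so the share that was polyadenylated may have differed, which was not tested. Reads shared between near-identical histone genes and a change in SMCs also stay open.

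Of 100 splits of the 9 libraries into 3 groups of 3, 1, the real one, gave as many genes as the 6287 that differed, and the highest other split gave 1996. A share of 1 of 100 argues against chance for that count. The splits cannot tell an effect of coculture from handling or library preparation that follows the groups. For each pair of groups 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, too few splits for a share under 0.05. The real counts were 3290, 4399 and 4673, and the highest other split gave 0 in each by limma, with at most 695, 516 and 850 genes at an unadjusted p under 0.05.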

How the results depend on the processing

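The alternatives with voom and with each library's trend on coding length removed were chosen after seeing the data. The alternatives on genes of mitochondrial DNA were not run, and robust eBayes and the minimum log2 difference of 1 were not applied to lists. Of 7660 values of named genes under the alternatives, 7462 kept their direction and side of the threshold, 167 lost a call, 8 gained a call and 23 reversed. Most named genes were picked for a large difference or a small p, so these counts do not describe all tested genes. Of 2304 list tests 2253 kept both, 21 lost a call, 28 gained a call and 2 reversed.

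With libraries rescaled to the same sum, genes higher and lower were 2858 and 1144 for the hMSC coculture against SMC alone, 1236 and 3746 for the MoS2-hMSC coculture against SMC alone, and 1059 and 5719 between the cocultures. The share of called genes that were higher moved from 44.9%, 48.2% and 46.6% to 71.4%, 24.8% and 15.6%. This scaling moved the median log2 difference of all genes from 0.004, -0.016 and -0.034 to 0.074, -0.097 and -0.183, because summed RPKM differed between the groups. Between the cocultures the 129 respiratory and mitochondrial ribosome genes then had 75 higher and 9 lower (median 0.16, above the median of all genes). A minimum log2 difference of 1 left 31 and 40, 32 and 37, and 4 and 2 genes, by its construction. With the trend on length removed 1523 genes were higher and 1379 lower between the cocultures. Of the 4673 genes called there without this removal, 2146 were also called with it. The cause of the other changes was not tested.

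Leaving out 1 library at a time gave 906 to 1569 higher and 1323 to 1916 lower genes for the hMSC coculture against SMC alone, 1636 to 2216 and 1702 to 2381 for the MoS2-hMSC coculture against SMC alone, 1798 to 2305 and 1830 to 2460 between the cocultures, and 5355 to 6260 that differed among the groups. The lowest count, 906, came without SMC-alone replicate 3, and 955 came without hMSC coculture replicate 3. A group left with 2 libraries takes its spread partly from the other groups. Over 8 alternatives 461 to 647 genes were higher and 678 to 841 lower after both cocultures.

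Reversed between the cocultures by rescaling to the same sum were CTSB (-0.02), PDIA4 (-0.004), DNAJB1 (-0.024), MT2A (-0.022) and GJA1 (-0.135). By quantile normalization they were CTSB (-0.155), TPI1 (-0.031), PKM (-0.054), HSP90AA1 (-0.053), MT1E (-0.028), FTL (-0.024), TAGLN (-0.008) and GJA1 (-0.13), and against SMC alone ENO1 (-0.065), MT1E (-0.093), VIM (-0.046) and TAGLN (-0.163) in the MoS2-hMSC coculture. By removal of the trend on length they were VCAN (0.031), MT1E (-0.058), MT1X (-0.088), MT2A (-0.258) and HIST1H2AC (-0.032) between the cocultures and MT1E (-0.124) in the MoS2-hMSC coculture against SMC alone. Of lists, glycolysis reversed between the cocultures by quantile normalization (camera adjusted p = 0.0286) and matrix genes in the MoS2-hMSC coculture against SMC alone by removal of the trend on length (camera adjusted p = 0.00586). The cause was not tested.

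Some lists that camera did not call passed its test under an alternative. Fry had called mitophagy (adjusted p = 0.00167) and the integrated stress response (0.0156) between the cocultures, fatty acid oxidation (0.00112) and the TCA cycle (0.003) in the hMSC coculture, and mitophagy (0.00119) and p53 and senescence genes (8.81e-04) in the MoS2-hMSC coculture against SMC alone. Between the cocultures, 7 of 22 alternatives called mitophagy (adjusted p from 0.0178 to 0.222), among them the replicate block (0.0392), only the 2 groups compared (0.0448), median-ratio scaling (0.0404) and leaving out SMC-alone replicate 1 (0.0491) or 3 (0.0443), while rescaling to the same sum turned its median to -0.066. The integrated stress response passed between the cocultures with no filter (0.0242) and without MoS2-hMSC coculture replicate 1 (0.0494; range 0.0242 to 0.265). In the hMSC coculture against SMC alone, fatty acid oxidation passed without SMC-alone replicate 1 (0.0496) or 3 (0.0489) or hMSC coculture replicate 3 (0.0345; range 0.0345 to 0.154), and the TCA cycle with libraries rescaled to the same sum (0.0168), after quantile normalization (0.0134) and without hMSC coculture replicate 1 (0.0384; range 0.0134 to 0.19). The ER unfolded protein response passed there with libraries rescaled to the same sum (0.0216) and after quantile normalization (0.00393; range 0.00393 to 0.338). In the MoS2-hMSC coculture against SMC alone, removal of the trend on length and quantile normalization called mitophagy (0.0356 and 0.0342; range 0.0342 to 0.17), and removal of the trend on length called p53 and senescence genes (0.0334; range 0.0334 to 0.47). Only quantile normalization called the ER unfolded protein response (0.00184), heat shock (0.0474), matrix proteases (0.00953) and cell cycle genes (0.0317) between the cocultures, with highest values of 1 each, and only a mean RPKM of at least 5 called epithelial markers in the hMSC coculture against SMC alone (0.0441; range 0.0441 to 0.955).

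With the replicate number as a block, genes higher and lower were 1319 and 1672, 2026 and 2158, and 2098 and 2307. Deviations from the group means correlated with r of -0.134 to 0.025 for libraries with the same number and -0.043 to 0.125 for others. How far read depth, from 34569842 to 50462898 reads, limits these calls was not tested.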

Other observations

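The TCA cycle had 2 of 17 genes higher and 0 lower after the hMSC coculture (median 0.046, camera adjusted p = 0.0959), 5 and 0 after the MoS2-hMSC coculture (0.057, 0.157), and 3 and 1 between the cocultures (-0.008, 0.946). Fatty acid oxidation had 2 of 18 higher and 6 lower (-0.097, 0.0622), 3 and 3 (-0.043, 0.84), and 6 and 1 (0.036, 0.344) in the same order. Glycolysis had 4 of 20 higher and 5 lower (0.015, 0.987), 3 and 4 (0.039, 0.662), and 5 and 4 (0.059, 0.569). The integrated stress response, called higher in the MoS2-hMSC coculture against SMC alone (12 of 20 higher, 0.196, 0.017, and adjusted p = 0.278 with an estimated correlation), had 4 higher and 2 lower after the hMSC coculture (0.067, 0.347) and 9 and 2 between the cocultures (0.139, 0.0757). The ER unfolded protein response had 4 of 16 higher and 0 lower (0.025, 0.219), 4 and 2 (0.052, 0.578), and 2 and 4 (camera adjusted p = 0.946), and the mitochondrial one 0 of 12 and 0 (-0.021, 0.981), 3 and 1 (0.001, 0.709), and 4 and 2 (-0.081, 0.946). HSPE1, the mitochondrial chaperonin subunit, was higher in the MoS2-hMSC than in the hMSC coculture, at 654.3 ± 15.8 against 471.2 ± 15.8 RPKM. Heat shock genes had 3 of 13 higher and 1 lower (0.037, 0.429), 4 and 3 (0.011, 0.662), and 2 and 1 (-0.059, 0.995), and metallothioneins 1 of 10 and 2 (-0.069, 0.547), 3 and 0 (0.032, 0.6), and 3 and 1 (0.132, 0.399).

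Cell state and marker groups were mixed. Synthetic and osteochondrogenic SMC genes had 6 of 14 higher and 3 lower after the hMSC coculture (median 0.064, camera adjusted p = 0.429), 4 and 4 after the MoS2-hMSC coculture (-0.044, 0.774), and 3 and 2 between the cocultures (-0.036, 0.995). RUNX2, a regulator of bone genes, was lower in the MoS2-hMSC coculture than in the hMSC coculture, at 10.0 against 13.8 RPKM. Interferon genes had 1 of 16 higher and 2 lower (0.03, 0.909), 2 and 2 (-0.034, 0.997), and 2 and 0 (-0.006, 0.946). Cholesterol genes had 4 of 21 higher and 1 lower (0.01, 0.439), 1 and 4 (0.028, 0.916), and 3 and 5 (-0.055, 0.944), and angiogenic factors 2 of 13 and 5 (0.003, 0.395), 2 and 5 (-0.058, 0.362), and 1 and 3 (-0.061, 0.946). The hMSC markers had 7 of 20 higher and 7 lower after the MoS2-hMSC coculture (-0.015, 0.997) and 1 and 4 between the cocultures (-0.056, 0.755). Epithelial markers had 1 of 5 higher and 2 lower (0.007, 0.813), 1 and 1 (0.139, 0.662), and 1 and 0 (0.156, 0.409), and leukocyte markers 0 of 2 and 1 (-0.278, 0.813), 0 and 0 (0.08, 0.726), and 1 and 0 (0.358, 0.639). Both tested chondrocyte and osteoblast markers had 0 calls in the 3 comparisons (camera adjusted p = 0.936, 0.916 and 0.995), and of the adipocyte markers 1 was tested, with no list test. Endothelial markers had 1 of 3 higher between the cocultures, EGFL7 (-0.102, 0.946).

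Between the cocultures, mitophagy genes had 7 of 15 higher and 1 lower (median 0.09, camera adjusted p = 0.0535, with a call under 7 of 22 alternatives), matrix proteases 1 and 4 of 15 (-0.037, 0.944), cell cycle genes 4 and 6 of 31 (-0.02, 0.946), p53 and senescence genes 6 and 2 of 17 (0.015, 0.301), immediate early genes 4 and 4 of 22 (-0.157, 0.588), NF-kB genes 6 and 6 of 28 (0.003, 0.946), lysosomal genes 4 and 3 of 21 (-0.019, 0.946) and histone genes 3 and 0 of 10 (0.249, 0.409). In the MoS2-hMSC coculture against SMC alone, mitophagy genes had 2 higher and 6 lower (-0.093, 0.129), p53 and senescence genes 3 and 7 (-0.102, 0.307) and targets of TGF-beta and YAP 6 and 4 (0.027, 0.662). Genes chosen after their values were seen, 6 in all, averaged at least 2 RPKM in SMC alone and under 1 RPKM in both cocultures: CSF2, FMOD, ODAPH, OLR1, SLC2A9 and SPINT2. The difference of each library from the mean of all other libraries was correlated with coding length. Spearman's rho was 0.352 to 0.506 in the hMSC coculture, -0.405 to -0.486 in the MoS2-hMSC coculture and -0.018 to 0.097 in SMC alone. For SMC alone the reference is mostly the 2 cocultures, whose trends are opposite, so these values cannot show that SMC alone has no trend.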
